A study of Mus musculus with 79 samples.

How the data were processed

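The series holds 79 mouse samples on the fate of neuro-mesodermal progenitors, the cells at the tail end of the embryo that give rise to both spinal cord and paraxial mesoderm. RNA was measured in 9 bulk libraries and in 53 single cells, and these are the samples analysed here. The 12 chromatin accessibility samples and the 5 chromatin immunoprecipitation samples were not analysed here. Per the labels' protocols, embryos were made from embryonic stem (ES) cell lines by tetraploid complementation, in which the embryo proper comes from the ES cells. Tissue was dissociated with trypsin and cells were sorted by flow cytometry on T (Brachyury), Sox2 or Tbx6.

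Bulk libraries came from 2 library kits. Per the labels' protocols, the sorted wild-type fractions T+, T+ Sox2+ and Sox2+ of Theiler stage 12 (TS12) were made with TotalScript from the RNA of few cells. The other 6 libraries, called the knockout table below, were made with the strand-specific ScriptSeq kit after ribosomal RNA depletion and from more cells. They are T+ cells of wild-type (WT) and T knockout (T KO) embryos at TS12 and TS13, and a pair of Tbx6+ libraries of TS14 titled WT and Tbx6 KO. RNA was treated with DNase on the column in both protocols. The cells were T+ Sox2+ cells of WT embryos at TS13, captured on a Fluidigm C1 chip. The labels name 55 capture sites with cells, and the table holds 53 cells. Samples were grouped by their labels. The titles and the source names of the Tbx6+ pair contradict each other on genotype, so that pair is named by its titles throughout.

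All deposited values are FPKM (fragments per kilobase of transcript per M mapped fragments), given by the authors as 1 value per gene symbol. Per the submitters' processing notes, the tools were TopHat2 2.1.0, Bowtie 1.1.2, Cufflinks 2.2.1 with Cuffdiff or Cuffnorm, bedtools 2.23.0, Picard 1.103 and SAMtools, on build mm10. The role of each tool, the annotation and the scaling between libraries are not given in the sources used here. The protocol names spike-in RNA for the cells, and no gene row used here is named for one. FPKM are not counts, so no count model was used. The 3 tables were taken as normalised separately. Each difference was therefore made within 1 table, and levels set side by side across tables are described as such.

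The number of fragments behind each bulk library was estimated from the values themselves. Where whole fragments are counted, the FPKM of a low gene times its length is a whole multiple of 1 step, and that step gives the depth. Between 14.2% and 41.1% of the low genes searched (823 to 2709 per library, up to 6000 bases long) lay within a relative tolerance of 0.0003 of such a multiple, up to 15 fragments, which is 120 to 1114 genes. With gene lengths shuffled, 7 to 17 genes did. The estimates run from 20.8 to 43.5 M fragments. A gene of 1 kb at 5 FPKM then rests on 104 to 217 fragments, and its counting error is 6.78% to 9.81% of its value. That error covers counting only, not embryos, sorts or library preparation, and amplified reads are not independent molecules. The cell table showed no such steps, so the depth of each cell is unknown.

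Differences are of log2(FPKM + 1) and understate the change of low genes. Each table holds 23983 gene symbols. Small RNA genes, numbered gene models, mitochondrial genes, ribosomal protein pseudogenes and symbols joining several genes were left out of counts and ranks, and 19772 symbols were kept. A gene was counted as higher or lower when the difference was at least 1 in size, that is 2-fold on that scale, among genes with at least 5 FPKM in 1 of the libraries compared. T, Sox2 and Tbx6 were left out of the counts over all genes because cells were sorted on them or lacked them. Tbx6 stayed in the counts and medians of the presomitic and paraxial mesoderm list, and its own list was also read without it. Every bulk group has 1 library, so these counts have no replicate error and no p-value and describe the libraries. Overlaps of lists are set beside the number that independent lists would share, n1 × n2 / N.

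One test was possible. limma 3.58.1 in R 4.3.3 was fitted with an empirical Bayes trend on log2(FPKM + 1) of the 4 T+ libraries of the knockout table, with stage and genotype as terms, for genes with at least 5 FPKM in 1 of them. It leaves 1 residual degree of freedom per gene, which is the difference of the genotype effect between the stages. P-values were adjusted by the Benjamini-Hochberg method and called at 0.05. They measure how alike the effect was at the 2 stages, not the spread between embryos of 1 genotype. Tested on simulated data of 8189 genes with noise of 0.15 (log2), this fit found 98 of 99 genes planted at 2-fold and 99 of 99 at 4-fold, with 6 false calls. The rule of at least 2-fold at both stages found 12 and 97 of them, with 0 false calls. Planted effects were equal at both stages, and the noise was the same for all genes. The shares found therefore do not carry over to genes whose effect differs by stage.

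Before the data were examined, 16 lists of pathway and state genes and 6 lists of cell type markers were fixed. They cover axial progenitors, presomitic and paraxial mesoderm, neural genes, Notch and the segmentation clock, Wnt targets, FGF targets, retinoic acid, anterior, central and posterior Hox genes, epithelial-mesenchymal transition, epiblast and pluripotency, proliferation, p53 targets, hypoxia and glycolysis, and dissociation stress. The marker lists are for notochord and node, endoderm, lateral plate and intermediate mesoderm, endothelium and blood, neural crest, and surface ectoderm. Some genes stand on more than 1 list. The median log2 difference of the members with at least 1 FPKM in the comparison was placed among 10000 random lists of the same size matched on mean expression, and lists outside percentiles 2.5 to 97.5 are described as standing apart. On simulated differences made from the T+ and Sox2+ libraries (11269 genes, 200 lists of 15), lists shifted by 1.5-fold were found high in 90.5% of cases and unshifted lists in 5%. For the T knockout, each list also has its limma calls, adjusted over all genes tested and over the list alone.

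Genes are named by a rule fixed in advance: the 10 largest differences in each direction per comparison, and members of the fixed lists. For the T knockout the rank is by the smaller of the 2 stage differences among genes that moved the same way at both stages. The genes above or below both the T+ and the Sox2+ fraction and the overlap genes are named because their counts are small, and they were chosen after their values were seen. The same holds for the Y-linked and imprinted genes.

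In single cells, a gene was called found at 1 FPKM or more, with an exact (Clopper-Pearson) 95% interval over cells. For a gene found in 0 cells the limit given is 3 cells of the total instead. The cells come from 1 sorted suspension and are not replicates, so they give no p-value. Correlations across cells are Spearman's rho of log2(FPKM + 1), placed among 10000 random gene pairs of like expression. On simulated pairs (9031 genes), a rank correlation of -0.6 was found low in 98.5% of cases, and unrelated pairs in 4.5%. The 5 genes with the highest and the 5 with the lowest rho with T and with Sox2 were taken from the 7252 genes found in at least 20% of cells and with a mean of at least 5 FPKM. No doublet caller was run.

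Alternatives were a pseudocount of 0.1 or 5, no FPKM filter or one of 20, median-ratio and upper-quartile scaling within a table, all gene rows kept, limma without trend, without the stage term or with a minimum fold of 1.5 (treat), list members of at least 5 FPKM, and other thresholds, filters and coefficients for the cells. Tables were computed with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots with matplotlib 3.10.9. A few genes that the naming rule picks are not reported here.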

Results

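RNA was profiled in cells sorted from the caudal end of mouse embryos, where neuro-mesodermal progenitors express both T (Brachyury), a T-box factor needed for mesoderm formation, and Sox2, a factor of neural and progenitor cells. The study asks how T and Sox2, and Tbx6 downstream, bear on the choice between neural and mesodermal fate. The 9 bulk libraries are 3 sorted WT fractions at TS12, 4 T+ libraries of WT and T KO embryos at TS12 and TS13, and 2 Tbx6+ libraries at TS14. There are no replicates: every bulk group has 1 library. Single-cell profiles came from 53 T+ Sox2+ cells of WT embryos at TS13. Estimated depth was 28.9, 23.3 and 28.6 M fragments for T+, T+ Sox2+ and Sox2+. It was 22.0 and 20.8 M for T+ WT and T KO at TS12, 40.1 and 31.5 M at TS13, and 34.2 and 43.5 M for the Tbx6+ libraries titled WT and Tbx6 KO.

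The genes behind the sorts and knockouts were read first. Sox2 was at 2.82 FPKM in T+ cells, 16.4 in T+ Sox2+ cells and 50.5 in Sox2+ cells. T mRNA was at 141, 341 and 192 FPKM in the same order, so the Sox2+ fraction held more T mRNA than the T+ fraction. The fractions are named by the sort, not by their mRNA. Tbx6, a T-box factor of presomitic mesoderm, was at 152, 173 and 47.9 FPKM. In T KO cells T was at 4.61 FPKM against 69.8 in WT at TS12, and at 3.32 against 76.4 at TS13. In the pair of Tbx6+ libraries, Tbx6 was at 10.2 FPKM in the library titled Tbx6 KO and 31.5 in the library titled WT, so the targeted gene was lower in the one titled Tbx6 KO. The labels give C57BL/6J for the T KO and Tbx6+ libraries and C57BL/6N for the others, which was not tested.

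**Figure D1:**
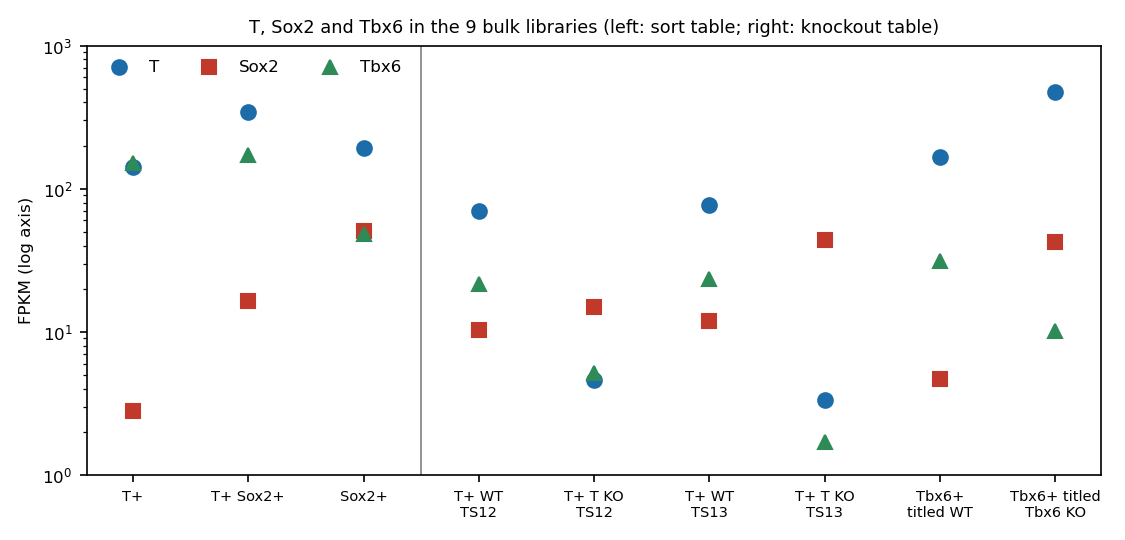
FPKM (log axis) of T, Sox2 and Tbx6 in the 9 bulk libraries, 1 point per library and gene, with no error bars because each group has 1 library. The grey line parts tables that were normalised separately. T lies at 4.61 and 3.32 FPKM in the T KO libraries and between 69.8 and 471 in the others.

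The first comparison asks how T+ Sox2+ cells differ from Sox2+ cells. T+ Sox2+ cells held more paraxial mesoderm transcripts: 17 of 19 measured genes of the presomitic and paraxial mesoderm list were at least 2-fold higher than in Sox2+ cells and 0 were as much lower, with a median log2 difference of 1.88. Msgn1, a master factor of presomitic mesoderm, was at 112 FPKM against 19.3. Meox1 and Foxc1, factors of the somites and their precursors, were higher by 3.12 and 2.51 (log2), and the protocadherin Pcdh19 by 2.92. Notch and segmentation clock genes had a median of 0.83. The ligand Dll1 was higher by 2.02 and the Notch modulator Lfng by 1.42.

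Neural genes were lower in T+ Sox2+ than in Sox2+ cells, with a median of -0.82. Of 14 measured, 6 were at least 2-fold lower, among them the SoxB1 factors Sox1 (5.28 against 28.3 FPKM) and Sox3 (6.61 against 31.1), and Irx3, a neural tube homeobox factor, at -2.01. Fabp7, a fatty acid binding protein of neural progenitors, was higher by 2.12, and Nes (0.17) and Foxb1 (0.02) were not lower. Among the other genes most reduced were Nkx2-9 (-3.11), a factor of the ventral neural tube, Olig3 (-2.52), a factor of dorsal neural progenitors, Hes3 (-2.91), a Hes repressor of axial and neural progenitors, Gdf10 (-2.76) and Cdh6 (-2.31). Tmem254c, Inafm2 and Ndufs5 also stood among the 10 lowest but were close to 0 in T+ Sox2+ cells (0.00741, 0.0163 and 0.000762 FPKM), and such a value can be a failed estimate. The other high ranks were Foxc2 (2.49), Gzmk (2.46), Nkd2 (2.45), an inhibitor of Wnt signalling, Dkk1 (50.5 against 9.98 FPKM), a secreted Wnt antagonist, and Mpzl2 (2.19). The globin Hba-a2 was higher by 2.96, but its near-identical copy Hba-a1 was lower, so its value is uncertain.

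Over 8273 compared genes, 125 were at least 2-fold higher in T+ Sox2+ than in Sox2+ cells and 119 lower. Axial progenitor genes had a median of 0.15 and a mean of -0.04, with Wnt3a at 1.18 and Nkx1-2 at -1.09. Posterior Hox genes had a median of 0.99, lateral plate and intermediate mesoderm genes 0.96 and endothelium and blood genes -0.88. Of these last, the globins Hba-x (-1.09) and Hbb-y (-1.04) were lower while Etv2 (1.12) and Kdr (0.62), of vessel precursors, were higher. List medians given here and below lay outside the central 95% of random lists unless said otherwise. Over all comparisons 109 of 174 list medians did, so standing apart was common. Random lists take genes singly and do not allow for list members that vary together. A pseudocount of 5 or a minimum of 20 FPKM moved most counts of this and the other comparisons by more than 1.5 times.

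The second comparison sets the same cells against T+ cells, which were low in Sox2. T+ Sox2+ cells held more of the axial progenitor genes, of which 12 of 17 were at least 2-fold higher and 0 lower, with a median of 1.87. Nkx1-2, a homeobox marker of caudal progenitors, was at 25.8 FPKM against 1.00. Cyp26a1, which degrades retinoic acid, was at 184 against 23.9, the caudal factor Cdx2 at 108 against 22.5, and the ligands Fgf8, Fgf17 and Wnt3a were higher by 1.87, 2.18 and 1.88. Neural genes had a median of 0.87, led by Sox3 (2.44) and Sox1 (2.41). Presomitic and paraxial mesoderm genes had a median of -0.31 and 4 of 20 at least 2-fold lower, Aldh1a2 (-1.39), Meox1 (-1.13), Foxc2 (-1.13) and Mesp2 (-1.05).

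T+ cells held more transcripts of other mesoderm. Of 11 lateral plate and intermediate mesoderm genes, 10 were at least 2-fold lower in T+ Sox2+ cells (median -2.14), among them Prrx1 (-2.97), a limb and lateral mesoderm factor, Osr1 (-2.88), a factor of intermediate mesoderm, Hand2 (-2.63) and Foxf1 (-2.56), a factor of splanchnic mesoderm. Of 12 endothelium and blood genes, 11 were lower (median -2.84). The embryonic globin Hba-x was at 40.6 FPKM against 5119, the red cell anion exchanger Slc4a1 at 0.576 against 63.8, and the vessel cadherin Cdh5 at 0.205 against 14.5. The other lowest genes included the globins Hba-a2, Hbb-y, Hbb-bh1 and Hba-a1, the metallothioneins Mt2 (-5.41) and Mt1 (-4.79), and Alas2 (-4.21) of red cells.

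Of 8293 genes, 108 were at least 2-fold higher in T+ Sox2+ than in T+ cells and 156 lower. Besides those named, the 10 highest were Hes3 (2.37), Pmaip1 (3.04), a p53-responsive inducer of apoptosis, Sema3a (2.60), a repulsive guidance ligand, Slain1 (2.50), Grhl3 (2.43), a surface epithelium factor, and Amd2 (4.49). Amd2 is a near-identical copy of Amd1, which stood at -1.80, so both are uncertain. FGF target genes had a median of 0.62, retinoic acid genes 0.40, epiblast and pluripotency genes 0.71, hypoxia and glycolysis genes 0.28 and endoderm genes 0.62. Epithelial-mesenchymal transition genes had a median of -0.29 (Twist1 -2.84, Snai2 -1.58, Cldn6 1.43), dissociation stress genes -0.52, and notochord and node genes -0.54.

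The third comparison sets the T+ fraction against the Sox2+ fraction. T+ cells exceeded Sox2+ cells in genes of the mesoderm lists: presomitic and paraxial mesoderm (median 1.88, 17 of 20 at least 2-fold higher), lateral plate and intermediate mesoderm (3.09, 11 of 11) and endothelium and blood (2.87, 12 of 12). Osr1 was at 38.5 FPKM against 1.06, Meox1 at 28.6 against 0.555 and Foxf1 at 24.4 against 0.851. Sox2+ cells exceeded T+ cells in neural genes (median of the difference -1.37, 9 of 14) and axial progenitor genes (8 of 17). Hes3 was at 45.7 FPKM against 0.208, Nkx1-2 at 56.3 against 1.00, Sox1 at 28.3 against 0.180, and Sox3 at 31.1 against 0.403.

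In that comparison 306 genes were at least 2-fold higher in T+ than in Sox2+ cells and 272 lower, of 8386. Globins and red cell genes led the higher genes (Hba-x 5.86, Hbb-bh1 5.50, Slc4a1 5.12, Hbb-b2 4.56, Alas2 4.41), with Mt2 at 4.66, and Hbb-y was at 4508 FPKM against 91.8. Hba-a2 and Hba-a1 were also among the 10, as an uncertain pair. The lower genes further included Sema3a (-4.45), Pmaip1 (-4.31), Cdh6 (-3.83), Nkx2-9 (-3.64) and Lrp2 (-3.37), an endocytic receptor of neuroepithelium. Notch genes had a median of 1.12, notochord and node genes 1.27, FGF targets -0.54 and surface ectoderm genes -1.17. Proliferation genes had -0.13. P53 targets (-0.11) and neural crest genes (-0.24) lay inside the range of random lists.

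Few genes of T+ Sox2+ cells lay above or below both the T+ and the Sox2+ fraction. The 15 at least 2-fold above both, of 8055 genes, included the ligands Fgf3, Fgf4, Fgf15 and Wnt3a, and Fabp7. Fgf3 was at 20.6 FPKM, against 4.89 in Sox2+ and 8.15 in T+ cells, and Wnt3a at 38.2 against 16.3 and 9.62. Also among them were Msmp, S100a16, Rab8b, Npm3, Uap1l1, Blnk, Chst7, AW551984 and Amd2. The 11 below both were Rsc1a1, Amd1, Slc29a1, the imprinted gene Mest with its neighbour Copg2, the RNA Rmrp, Mt1, Coro2b, and the globins Hba-a1, Hba-x and Hbb-y. Both comparisons use the T+ Sox2+ library and share its chance values. Independent lists would share 1.68 and 0.434 genes, but these lists are not independent. Simulated counting error alone gave 0 and 0. Deviations of the libraries from their gene means, drawn at random and so holding real differences too, gave 97.9 and 73.4 on average. With 1 library per fraction, chance values and real differences cannot be parted. The 15 and 11 are thus not shown to be an excess.

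**Figure D2:**
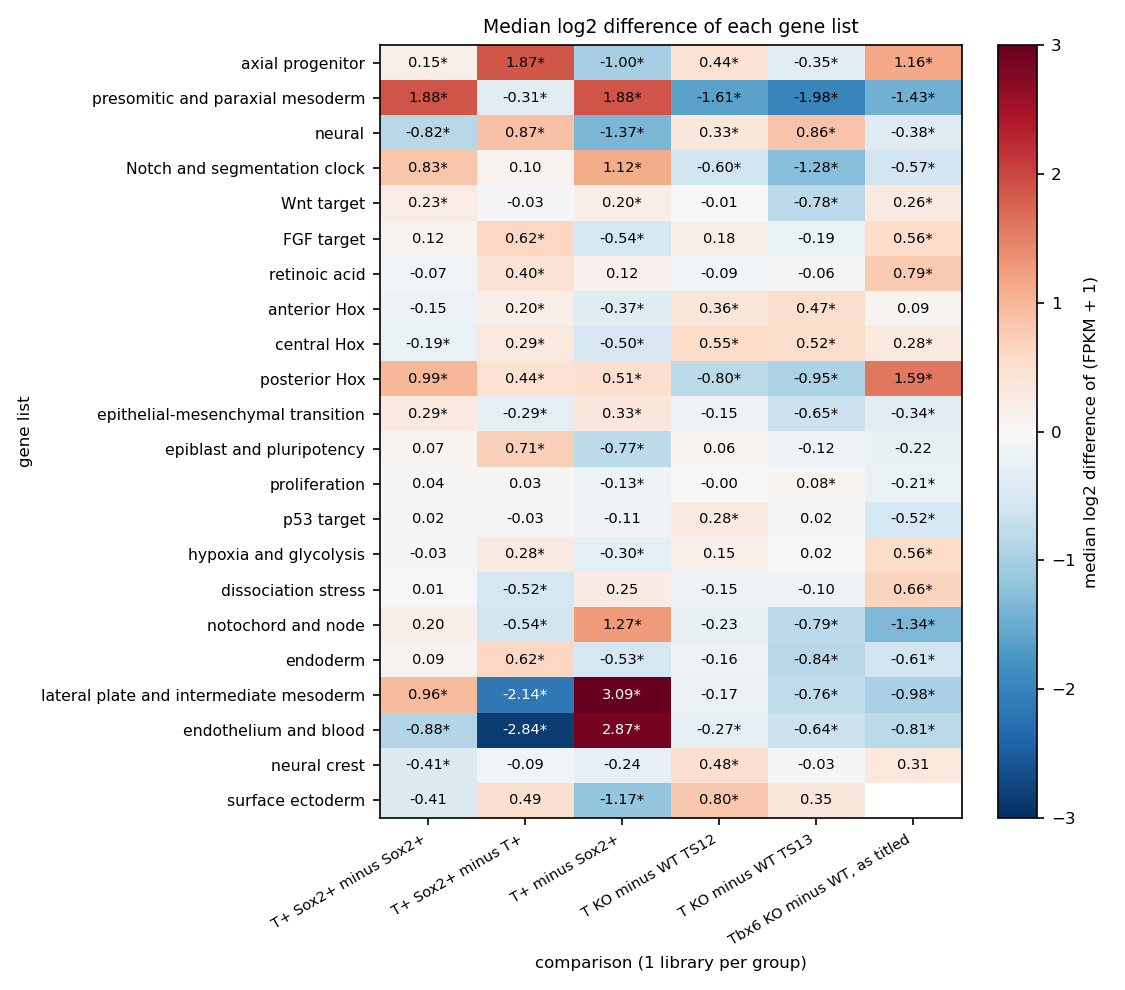
Median log2 difference of (FPKM + 1) of the fixed gene lists in 6 comparisons of 1 library with 1 library. Stars mark medians outside the central 95% of random lists matched on expression, and an empty field is a list with too few measured members. The presomitic and paraxial mesoderm list reads 1.88 for T+ Sox2+ against Sox2+ and -1.61 and -1.98 in the T knockout.

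The next comparison asks how T+ cells differ without T. Presomitic mesoderm genes fell as a group: of 12 list members tested over both stages, 10 fell and 0 rose in limma's test with Benjamini-Hochberg adjustment, and 12 fell when adjusted over the list alone. Msgn1 fell by 4.01 (log2, SE 0.186, adjusted p = 1.6e-06), from 56.9 to 3.48 FPKM at TS12 and from 42.5 to 1.18 at TS13. Dll1 fell by 2.75 (SE 0.172, adjusted p = 1.7e-05) and Rspo3, a secreted enhancer of Wnt signalling, by 2.42 (SE 0.173, adjusted p = 4.3e-05). Also among the 10 were Pcdh19 (-2.27), Dkk1 (-2.19), Meox1 (-2.12), Aldh1a2 (-1.50), Foxc1 (-1.43), Dll3 (-1.34) and Cited1 (-1.33). Tbx6, left out of the test, was at 5.13 FPKM against 21.4 at TS12 and 1.70 against 23.2 at TS13. Without the stage term 10 genes of all 8189 tested fell, against 69 with it.

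Some Notch and other mesoderm genes also fell in the limma test, and most did not pass. Of 12 Notch and segmentation clock genes 4 fell, Dll1, Dll3, Nrarp (-1.32) and Hey1 (-1.02), and 9 when adjusted over the list alone. Dll1 and Dll3 are on the presomitic list too and were counted there above. Of 9 lateral plate genes 2 fell, Foxf1 (-1.24) and Osr1 (-1.21), and 3 over the list alone. Of 4 epiblast genes 1 fell, Pou5f1 (-1.83), with the same count over the list alone. Outside the lists the genes that fell included Mixl1 (-2.46), a homeobox factor of the primitive streak, the ligand Fgf3 (-2.27), Arg1 (-3.98), an arginase, Frzb (-1.65), a Wnt antagonist, Rftn1 (-2.07), and Dppa3 (-2.13), a germ cell gene.

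A few progenitor and neural genes rose in T KO cells, and most of the rising calls named in this paragraph need the stage term. Without it 3 genes of all tested rose, against 54 with it. Of 18 axial progenitor genes 4 rose, Hes3 (2.58, SE 0.280, adjusted p = 0.0012), Nkx1-2 (1.16), Wnt8a (1.52) and Sp8 (0.79), and 1 fell, Cyp26a1 (-2.67). Over the list alone 5 rose and 3 fell. Of 8 neural genes 2 rose, Sox3 (1.61) and the adhesion molecule Ncam1 (0.80), and over the list alone 4 rose and 2 fell. Of 12 central Hox genes 2 rose, Hoxc6 (0.78) and Hoxb9 (0.75), and 9 over the list alone, where 3 fell. Crabp2, which binds retinoic acid, rose by 1.15. With it, 1 of 6 retinoic acid genes rose and 2 fell, the same over the list alone. Sema3a (1.39), Zic2 (1.31), Cdc25b (1.41), Bmf (1.42) and Mt1 (1.49) rose as well. Sox2 itself was at 14.9 FPKM against 10.2 at TS12 and 43.5 at TS13, where it was higher than in WT by 1.78 (log2).

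The remaining lists had few or no calls. Of 12 Wnt targets Sp8 rose and Dkk1 fell, with 1 rising and 2 falling over the list alone. In limma, 0 genes passed among the FGF targets (10 tested), anterior Hox genes (15), epithelial-mesenchymal transition (9), proliferation (16), p53 targets (9), hypoxia and glycolysis (12), endoderm (6), endothelium and blood (8), and dissociation stress, notochord and node and neural crest genes (3 each). Over the list alone, 5 anterior Hox genes rose and 1 fell, 4 genes of the transition list fell, 3 endoderm and 2 blood genes fell, and 1 FGF target, 1 hypoxia gene and 1 neural crest gene rose. The notochord list then had 1 rising and 1 falling. Fewer than 3 members of the posterior Hox and surface ectoderm lists were tested.

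In all, 54 genes rose and 69 fell of 8189 in the limma test, and 1030 had an unadjusted p under 0.05. The labels also give different strains for the WT and T KO libraries. The Y-linked genes Eif2s3y (4.70), Ddx3y (3.28) and Uty (3.15) rose, and the imprinted RNAs Rian (-6.52), H19 (-5.30) and Meg3 (-4.36) fell. H19 was at 338 and 578 FPKM in WT at TS12 and TS13, and at 7.95 and 13.1 in T KO. In the sort table, which was normalised separately, H19 was at 2.03 to 9.69 FPKM. Genotype and strain label cannot be parted in the T+ libraries of the knockout table, and the Tbx6+ libraries are set beside them further below. The calls rest on 1 residual degree of freedom: without the stage term 3 genes rose and 10 fell, and with a minimum fold of 1.5 6 rose and 21 fell.

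Counted per stage, 78 genes were at least 2-fold higher and 78 lower in T KO at TS12 (7867 genes), and 88 and 117 at TS13 (7955). Upper-quartile scaling gave 60 and 90 at TS12. Compared with the WT library of TS13 instead, T KO at TS12 had 47 higher and 104 lower genes. At both stages 23 genes were higher and 39 lower, where independent lists would share 0.479 and 0.791. Without Y-linked and imprinted genes the counts were 20 and 33. The opposite direction held for 1 gene, Rnaset2a, a member of a near-identical pair. Across 7633 genes the differences at the stages correlated with r = 0.473 and rho = 0.295. Genes are not independent replicates. The T+ WT library of TS12 also had 1043 of 1477 sensory receptor genes above 0, against 23 to 36 in the other libraries.

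**Figure D3:**
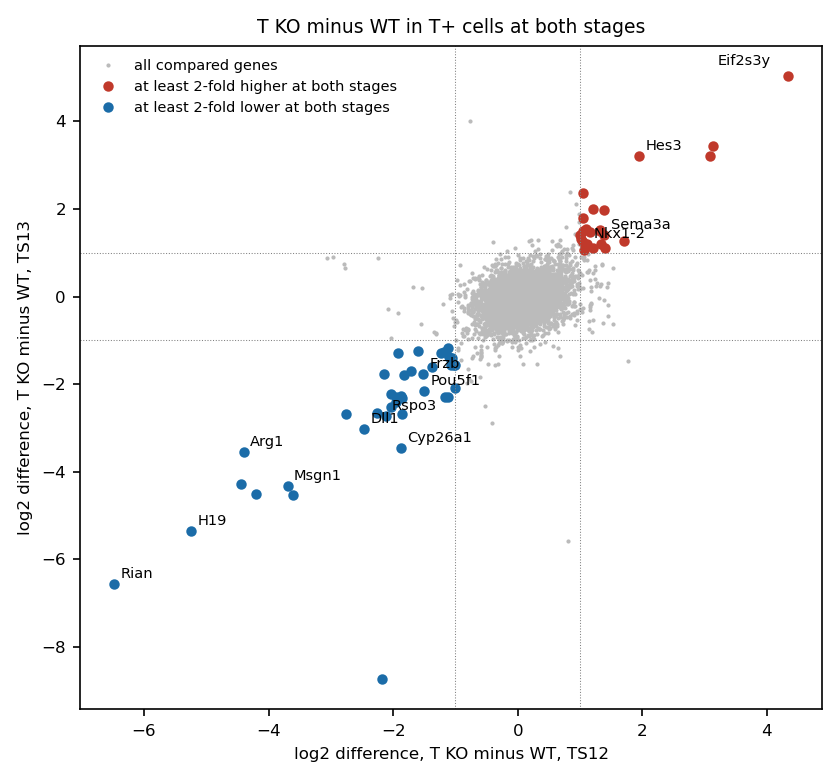
Log2 difference of (FPKM + 1) between T KO and WT T+ cells at TS12 (x axis) and TS13 (y axis), 1 point per gene, 1 library per group. Red points are the 23 genes at least 2-fold higher and blue points the 39 lower at both stages. Msgn1 lies at -3.69 and -4.32, Eif2s3y at 4.34 and 5.05.

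Presomitic genes had a median of -1.61 at TS12 (10 of 17 at least 2-fold lower) and -1.98 at TS13 (14 of 16), with Tbx6 among the lower genes at both. Notch genes had -0.60 and -1.28, Wnt targets -0.01 (inside the range of random lists) and -0.78, and neural genes 0.33 and 0.86. Lists of other cell types were lower at TS13 too: endoderm -0.84 (-0.16 at TS12), lateral plate and intermediate mesoderm -0.76 (-0.17), notochord and node -0.79 (-0.23), epithelial-mesenchymal transition -0.65 (-0.15), and endothelium and blood -0.64 (-0.27). Of their TS12 values only the last lay outside the range of random lists. At TS13, Sox1 was at 9.98 FPKM in T KO against 0.569 in WT, and Irx5 at 4.86 against 0.799, while the neural genes Hes5 (-1.64) and Fabp7 (-1.57) were lower. Of the axial progenitor list, Wnt3a was at 1.66 FPKM against 18.6 at TS13, Fgf8 at 4.49 against 30.1, and Cyp26a1 at 6.12 against 77.6, while Wnt8a was at 8.55 against 1.22 and Fgf17 differed by -0.33. At TS12 Wnt3a and Fgf8 differed by -0.41 and -0.52, and over both stages neither passed the limma test (Benjamini-Hochberg adjusted p = 0.10 and 0.061). Central Hox genes had medians of 0.55 and 0.52, anterior Hox genes 0.36 and 0.47, posterior Hox genes, with 3 and 5 members measured, -0.80 and -0.95. Median and mean had opposite signs for epiblast genes at TS12 (0.06 and -0.34) and for dissociation stress (-0.10 and 0.30) and neural crest genes (-0.03 and 0.28) at TS13, all inside the range of random lists. The difference between the stages was not tested.

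From TS12 to TS13, T+ cells of each genotype were compared with themselves. In WT 75 genes were at least 2-fold higher at TS13 and 30 lower (7801 genes), and in T KO 54 and 65 (7923). Both genotypes had 12 higher and 4 lower genes in common, where independent lists would share 0.267 and 0.134. The higher ones were globins, Mt1 and Mt2, Slc4a1, Hoxa10, Igfbp5, Ndufa4l2 and Plagl1. The lower ones were Pou5f1, a pluripotency factor (9.72 FPKM at TS13 against 35.7 in WT, and a difference of -2.44 in T KO), Cdx1, Fst, an activin antagonist, and the histone Hist1h2ap. In WT, posterior Hox genes had a median of 1.24 (Hoxc10 1.63, Hoxd10 1.32, Hoxa10 1.24), central Hox genes 0.55 and endothelium and blood genes 0.68. Lefty2, a Nodal antagonist, was at 0.689 FPKM against 10.8. The other lowest genes were Snrpn, Zfp488, Grk4, Ap1s3 and Arsb, the receptor genes Vmn1r58 and Olfr613, and the pseudogene Olfr856-ps1. Zfp488, at 171 FPKM in WT at TS12, was at 15.0 to 27.2 in the other libraries, and Olfr613, at 45.3, was at 2.78 to 6.45.

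In T KO cells the TS13 library was lower in progenitor genes, with 8 of 18 axial progenitor genes at least 2-fold lower (median -0.80): Cdx1 (-2.39), Wnt3a (-2.29), Fgf8 (-1.73) and Sp5 (-1.41) led. Hes3 was at least 2-fold higher (1.62). Wnt targets had a median of -0.84, with the Wnt deacylase Notum at -1.78. Neural genes had 0.74, with Sox1 higher by 2.27. The other named genes were Gdf10 (2.01), Ndufa4l2 (2.11), Tmem59l (-1.90) and Akr1b3 (-1.86). Amd1 (-5.74), Hba-a2 (-5.65) and Hist1h2ap (-6.59) have near-identical copies and were at or near a listed 0 at TS13, so they are uncertain.

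The Tbx6+ pair asks how cells differ without Tbx6, and directions follow the titles. The library titled Tbx6 KO was lower in presomitic and paraxial mesoderm genes, 14 of 18 by at least 2-fold, with a median of -1.43. Tbx6 itself is 1 of the 14. Pcdh19 was at 0.213 FPKM against 19.2, Foxc1 at 1.71 against 41.7, Meox1 at 0.781 against 16.8 and Dll1 at 21.2 against 126. It was higher in axial progenitor genes, 10 of 17 by at least 2-fold, with a median of 1.16: Cyp26a1 was at 238 FPKM against 32.8 and Nkx1-2 at 38.6 against 4.73. T (471 against 166 FPKM) and Sox2 (42.3 against 4.70) were also higher there. Neural genes had a median of -0.38, which turned to 0.25 among members of at least 5 FPKM, so they have no clear direction.

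Posterior Hox genes were higher in the library titled Tbx6 KO, 9 of 11 by at least 2-fold (median 1.59), led by Hoxd12 (2.56), Hoxc11 (2.47), Hoxd11 (2.42) and Hoxa11 (1.82). Notch genes had a median of -0.57, with Nrarp, a feedback inhibitor of Notch, at -3.44. Notochord and node genes had -1.34, lateral plate genes -0.98 and p53 targets -0.52. FGF targets had 0.56, retinoic acid genes 0.79, hypoxia and glycolysis genes 0.56 (Bnip3 1.52) and dissociation stress genes 0.66, with the heat shock genes Hspa1a (2.43) and Hspa1b (2.36). Blood and endothelium markers split: the globins Hbb-y (7.39), Hbb-bh1 (5.49) and Hba-x (4.75) were higher while Kdr (-2.15), a receptor of vessel precursors, was lower, so the list's median is -0.81 and its mean 0.83.

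Of 7723 genes, 191 were at least 2-fold higher in the library titled Tbx6 KO and 123 lower. The highest further included H19 (4.55), Igfbp3 (4.05), Pmaip1 (3.82), Rgs4 (3.66), Gpr128 (3.38), and Hba-a2 and Rps27, both with near copies. The lowest included Frzb (-3.61), Fst (-3.09), Plxna2 (-3.09) and Nkd2 (-3.02), and Gzmk and Dppa3, which are listed at 0 there.

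The T and Tbx6 knockouts shared lower genes, counted over all genes. Lower in T KO at both stages and in the library titled Tbx6 KO were 15 genes of 7184, where independent lists would share 0.405: Msgn1, Dll1, Meox1, Foxc1, Pcdh19, Dkk1, Nrarp, Frzb, Foxf1, Pou5f1, Plxna2, Adam19, Lhfp, Eogt and Dppa3. Higher in both were 4 (0.197 for independent lists), Nkx1-2, Sema3a, Bmf and Tcea3. Lower in T KO but higher in the library titled Tbx6 KO were 7 (0.486), Cyp26a1, Arg1, Uap1l1, Amph, the imprinted Rian and H19, and Hba-a2. Rian was at 1.95 and 8.39 FPKM in the Tbx6+ libraries titled WT and Tbx6 KO, both far below T+ WT (107 and 110). Hba-a2 is uncertain because of its near-identical copy. Higher in T KO but lower in the library titled Tbx6 KO was 1 gene, Eif2s3y (0.165). Overlaps in opposite directions thus also exceeded the number for independent lists. Exceeding that number does not by itself show a shared effect of the knockouts.

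The knockout genes were also set against the sort. Of the genes lower in T KO at both stages, 19 were at least 2-fold higher in T+ than in Sox2+ cells, where independent lists would share 0.733, among them Meox1, Foxf1, Pcdh19, Foxc1, Msgn1, Dll1 and Dkk1. Of those higher in T KO, 11 were higher in Sox2+ than in T+ cells (0.357), among them Hes3, Nkx1-2, Sox3, Sema3a, Zic2 and Crabp2; upper-quartile scaling left 7. The contrary pattern held for Cyp26a1, lower in T KO and higher in Sox2+ cells, and for Hba-a1 and Mt1 the other way.

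Single cells can show which transcripts meet in 1 captured cell. These cells were sorted on T and Sox2, so finding those genes together is no test of it. No doublet caller was run. T was found in 53 of 53 T+ Sox2+ cells (93.3 to 100%), with a median of 311 FPKM, and Sox2 in 46 (86.8%, 74.7 to 94.5%), with a median of 21.2. Tbx6 was found in 46 cells, and Sox2 and Tbx6 together in 41 (77.4%, 63.8 to 87.7%), where independent genes would share 39.9. The signalling genes Fgf8, Rspo3 and Dll1 and the mesoderm gene Cited1 were found in all 53, Wnt3a in 50 and the clock gene Hes7 in 49. Of the presomitic and paraxial mesoderm list, 11 of 22 genes were found in most cells and 4 in none, with Msgn1 in 15 cells, Tcf15 in 10 and Meox1 in 4. Of 22 neural genes only Ncam1 (50 cells) and Foxb1 (44) were found in most cells and 7 in none, with a median of 4 per cell. Sox3 was found in 22 cells and Sox1 in 5. Nkx1-2 was found in 12 cells, each of which also had Tbx6, where independence gives 10.4. Intervals cover counting over cells only.

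**Figure D4:**
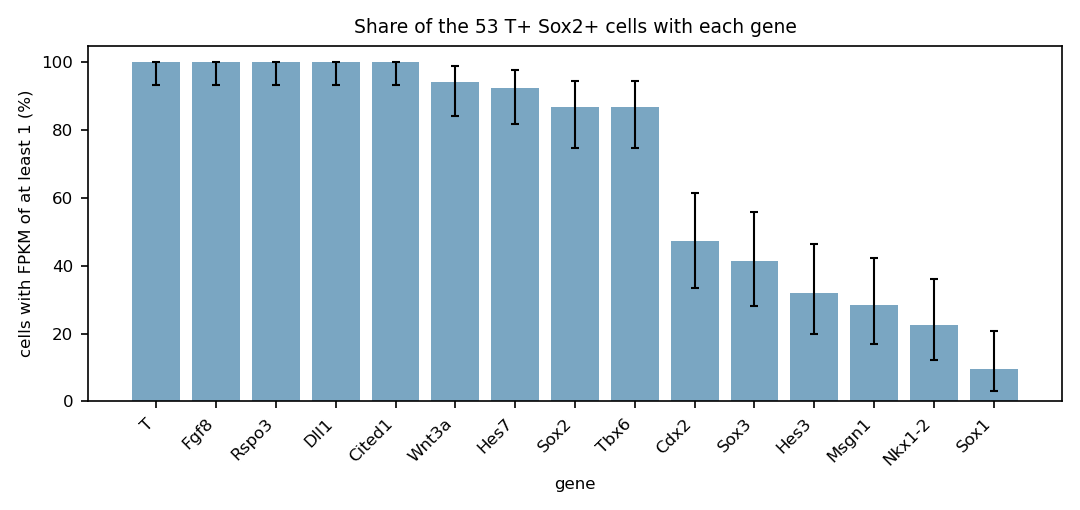
Share of the 53 T+ Sox2+ cells with at least 1 FPKM of each of 15 genes, with exact 95% intervals over cells. T, Fgf8, Rspo3, Dll1 and Cited1 are at 100%, Sox2 and Tbx6 at 86.8%, and Msgn1 at 28.3%.

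All 16 proliferation genes, all 12 central Hox genes and all 10 FGF targets were found in most cells, and 0 of 12 posterior Hox genes. Of the lateral plate list 5 of 13 were, 1 was in none, and a cell had a median of 6. Foxf1 was found in 46 cells, Msx2 in 48 and Hand1 in 36. The globins Hbb-y, Hba-x and Hbb-bh1 were found in 0 of 53 cells, which allows up to 5.66% (3 cells of 53). A cell held a median of 5902 found genes (4075 to 9001).

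T and Sox2 levels across these cells had a rank correlation of -0.148 (rho, percentile 17.4 of random gene pairs, inside the central 95%). The cells were sorted on both genes, and the random pairs were not. The value therefore cannot decide whether T and Sox2 oppose each other outside this sort. Their Pearson correlation of log values was -0.233, and in cells with both genes rho was -0.0649. The strongest partner of T was Cited1, with a rho of -0.661, followed on the low side by Gmpr (-0.567), the histone H2afz (-0.532), Timm13 (-0.530) and Txlng (-0.525). Highest with T were Ggnbp2 (0.519), Dst (0.492), Atp13a1 (0.466), Hmmr (0.450) and Adat1 (0.445). Sox2 was highest with Arhgap24 (0.541), Ddah2 (0.533), Rrp15 (0.515), Tbc1d1 (0.500) and Mrpl48 (0.474), and lowest with Ptpla (-0.500), Med1 (-0.479), Mms19 (-0.477), Fbxo28 (-0.446) and Edem1 (-0.436). These extremes are the ends of 7252 genes. The mean levels of the presomitic and neural lists correlated at 0.423, and each followed the number of genes found in the cell (0.711 and 0.562).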

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

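All tests in this part were chosen only after the result was seen, except those of genomic DNA and of transcription for the receptor genes.

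Among lists outside the range of random lists at both stages and genes at least 2-fold apart at both, the effect of the T knockout went opposite ways at the 2 stages for 1 list and 1 gene, and the difference was not tested. The axial progenitor list had a median of 0.44 at TS12 and -0.35 at TS13, a difference of -0.78. Rnaset2a was higher in T KO at TS12 and lower at TS13, a difference of -3.24, and it shares sequence with Rnaset2b. A signal outside the comparisons appeared in 1 library: 1043 of 1477 sensory receptor genes, which mesoderm is not known to use, were above 0 in the T+ WT library of TS12, against 23 to 36 in the other 8.

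For the receptor genes, deeper sequencing is argued against because 7 of the 8 other libraries are deeper. Transcription of receptor genes in particular was to give a ratio of found shares of at least 1.5. Among genes at 0 in the other 8 libraries, 69.8% of 1356 receptor genes and 65.0% of 2075 other genes were found. The ratio was 1.08. With 65.0% of other genes found, almost all receptor genes would have been needed to reach 1.5, so this ratio cannot decide. The shares show only that the signal was not confined to receptor genes. Genomic DNA cannot be told apart from other sources. The receptor medians of 13 autosomes varied 2.94-fold, from 0.0493 to 0.145 FPKM. That lies between the 2-fold that 1 even source would give and the 5-fold that would exclude it. In the T+ WT library of TS12, 1 fragment of a 1 kb gene is 0.046 FPKM. The medians thus rest on few fragments, and their spread cannot decide. X-linked genes, at 1 copy in male cells, had a mean of 0.0525 FPKM against 0.110 for autosomal ones, and the sex of the WT line was not tested. No biological explanation was tested.

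For the Y-linked genes, loss of T is argued against: the library titled WT of the Tbx6+ pair, with T at 166 FPKM, had a Y-linked median 1.56 times that of the T KO libraries. Different ES cell lines may account for them, since their median was at least 10.3 FPKM in the T KO and Tbx6+ libraries, while the highest single value in the 5 WT-line libraries was 0.373. A line that lost or lacks the Y chromosome would look the same, and which of them holds was not tested. For the imprinted genes of the Dlk1-Dio3 region, Rian and Meg3 among them, loss of T is argued against too. Their median was 0.392 and 1.15 FPKM in the Tbx6+ libraries titled WT and Tbx6 KO, with T at 166 and 471 FPKM. It was 0.145 and 0.186 in T KO, and 15.96 to 26.2 in the 5 WT-line libraries. The Tbx6+ libraries differ from the others in sort and stage too. H19 stays open, since it was at 43.2 and 1036 FPKM in the Tbx6+ libraries.

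Posterior Hox genes stood higher in the sort table than in the T+ WT libraries of the knockout table, and the tables were normalised separately. Library kit or table normalization as the whole cause is argued against: the posterior shift exceeded the central one by 2.49 (3.10 against 0.61, interquartile ranges 2.30 and 1.56), and all genes shifted by 0.07. A later stage of the sorted embryos may account for it and cannot be told apart from other differences between the tables. The lowest posterior median of the 3 fractions was 1.42 FPKM, against 0.550 and 0.382 in T+ WT at TS12 and TS13, and Pou5f1 was at most 2.48 against 35.7 and 9.72. It stays open because the median over all 12 genes, most of them near 0, was not higher at TS13 than at TS12, while the 5 with at least 1 FPKM were each higher.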

How the results depend on the processing

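The reference from TS13, the receptor level taken off, the counts without Y-linked and imprinted genes and the list medians without Tbx6 were chosen only after the data were seen. No paired analysis was possible because every bulk group has 1 library and no label pairs libraries by replicate or source. The limma fit compares genotypes within stage. Of 214 alternative values of the summary results 133 stayed within 1.5 times or within their interval, 81 moved and 0 reversed. Median-ratio scaling kept 27 of 27, upper-quartile scaling 23 of 24 and a pseudocount of 0.1 24 of 27. For named genes 1269 values stayed and 363 moved, and for list medians 507 stayed and 24 moved. With members of at least 5 FPKM, 2 medians reversed in the Tbx6+ pair, neural genes to 0.25 and endothelium and blood genes to 5.12. Stricter settings count fewer genes by construction; otherwise the cause was not tested. Counting error of 6.78% to 9.81% at 5 FPKM and the lack of replicates limit all of these values.

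With a pseudocount of 5, counts of higher and lower genes were 62 and 52 for T+ Sox2+ against Sox2+, 49 and 92 against T+, 186 and 153 for T+ against Sox2+, 33 and 38 for T KO at TS12, 32 and 54 at TS13, 20 and 25 for the stages in T KO, and 89 and 54 for the Tbx6+ pair; 32 were higher at TS13 in WT. Above and below both fractions were 3 and 6, both stages had 10 and 21, the T and Tbx6 knockouts shared 1 and 6, the sort shared 4 and 9 with the T knockout, and limma had 34 rising.

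With at least 20 FPKM the counts, in that order, were 60 and 49, 42 and 49, 110 and 95, 36 and 27, 21 and 42, 19 and 28, and 85 and 41, with 44 and 14 for the stages in WT. Above and below both were 8 and 7, both stages had 7 and 11, the knockouts shared 2 and 3, the sort 3 and 5, and limma had 9 and 13.

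With no FPKM filter, 199 were higher in T+ Sox2+ than in Sox2+, 193 and 286 were higher and lower than in T+, 168 were lower in T KO at TS12, and 173 were higher at TS13. The value was 505 for T+ minus Sox2+ at TS12: higher, 421 for T+ minus Sox2+ at TS12: lower and 218 for T KO minus WT in T+ cells at TS13: lower. For the stages 76 were lower in WT, and 107 and 134 differed in T KO. The Tbx6+ pair had 199 lower, and 322 for Tbx6 KO minus WT, as titled, at TS14: higher. Both stages had 70 lower, the knockouts shared 23 lower, the sort 33 lower, and limma had 237 rising and 350 falling.

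A pseudocount of 0.1 gave 37 higher at both stages, 9 higher in both knockouts and 19 higher in T KO and in Sox2+ cells, where upper-quartile scaling gave 7. Upper-quartile scaling gave 60 and 90 for T KO at TS12 beside 78 and 78. With all gene rows kept, 48 were lower at TS13 in WT and 84 higher in T KO. Against the WT library of TS13, T KO at TS12 had 47 higher; both stages had 19 and 56, of which 11 and 36 were shared with the 23 and 39. With the receptor level taken off, T KO at TS12 had 93 and 71. Without the stage term limma had 3 and 10, with a minimum fold of 1.5 6 and 21. At 10 FPKM, Sox2 and both genes were found in 69.8% of cells. Leaving out cells with under 0.5 of the median number of found genes removed 0 cells, so it tests nothing.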

Other observations

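All values in this part were chosen only after they were seen, and none has a test.

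The genes below are single members of fixed lists and do not stand for their lists. Slc2a1, a glucose transporter of the hypoxia and glycolysis list, was at 474 FPKM in Sox2+ cells, 192 in T+ Sox2+ cells and 112 in T+ cells, while the other members of its list differed by -0.18 (Bnip3) to 0.16 (Ldha) between T+ Sox2+ and Sox2+ cells. Fn1, the fibronectin of the mesenchymal matrix, was at 147, 307 and 445 FPKM in the same order, and the adhesion gene Ncam1 at 94.9, 52.6 and 28.3. Bmp4, a ligand of lateral and ventral mesoderm, was at 5.21, 11.0 and 52.0. Each gene was in between in T+ Sox2+ cells.

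In single cells, Pcna and Mcm2, genes of DNA replication, had a rho of 0.409 and 0.380 with Sox2, and the mitotic genes Aurka and Ccna2 had 0.316 and 0.302. These were 4 of 16 proliferation genes, where chance gives 0.8 on average, and the other 12 lay inside the central 95% of random pairs. The list was singled out after its values were seen, and whether its genes vary independently was not tested. With T, Pcna had -0.363, Hey1, a Notch effector, -0.373, Cdx2 -0.330, and the lateral mesoderm genes Hand1 and Foxf1 -0.326 and -0.313. Of 168 genes compared, 7 lay outside that range with T and 11 with Sox2, where chance gives 8.4, so the genes as a whole are not set apart from chance.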
